A study of Mus musculus with 64 samples.

How the data were processed

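RNA of liver and of liver tumours from male C57BL/6 mice was hybridised to Illumina mouse expression arrays. Per the labels' protocols, the mice had received 50 mg/kg of diethylnitrosamine, a carcinogen that gives rise to hepatocellular tumours, at 2 weeks of age. From 44 weeks of age they were treated for 28 days by gavage, with 2 doses per day, and tissue was taken at 48 weeks after a 3 h fast. The last dose of BEZ235 was given 1 h before sacrifice and the last dose of RAD001 at the start of the fast. The treatments were placebo, BEZ235 at 30 mg/kg, RAD001 at 10 mg/kg, and a combination of 2.5 mg/kg RAD001 with 18 mg/kg BEZ235.

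The deposited values are linear probe intensities from which the authors had subtracted background, processed in BeadStudio per the submitters' processing notes. The BeadStudio version, the scanner settings and the chip that held each sample are not given in the sources used here. Within a treatment all arrays, liver and tumour together, held the same brightest intensities rank by rank, with a log2 range of 0, while the range over all arrays was 0.133. The values thus carry a quantile normalization of each treatment on its own. The median intensity of an array, in linear units, was 9.69 for placebo, 9.28 for BEZ235, 9.45 for RAD001 and 9.35 for the combination.

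A second, non-normalized table holds 128 further value columns. Its column names match no sample label, so it was not used here. For that reason neither negative control probes nor detection p-values could be used, and the neqc normalization fixed beforehand was replaced by its closest equivalent on the deposited intensities. All 64 arrays were quantile-normalized together. A normexp background correction followed, with the background mean set to 0, its SD set to 7.03 from the negative values mirrored at 0, and an offset of 16, and log2 was taken. A fit of all 3 normexp parameters to the values (the saddle-point method) was added as an alternative after the data had been seen.

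Of 25697 probes, 23978 carried 1 gene symbol, 0 carried several and 1719 carried none in the platform annotation. Symbols were updated through the Entrez number, which matched for 23962 probes and failed for 16, which kept the older symbol. A probe was kept when it exceeded 2 noise SDs, an intensity of 14.1, on at least 6 arrays, which left 15241 probes, 896 of them without a gene. The probe with the highest mean stood for a gene with several probes, which held for 2727 of the 10493 genes tested. Among 1137 genes that differed between placebo tumour and placebo liver and had several kept probes, 153 had probes that differed in sign.

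The animal was the replicate. Tumours of an animal were averaged on the log2 scale, which gave 1 value per animal and tissue. No pair of arrays was a duplicate. The number that starts each sample title names the mouse, so that liver and tumour of a number come from the same animal. The within-animal correlation estimated from the data was 0.0968. For that reason the comparison of tumour with liver, and those of a treatment effect between both tissues, used all 8 groups with the animal as a random block. Treatments were compared within the 4 tumour groups or within the 4 liver groups. Tests were limma's moderated test on log2 values, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a limit of 0.05 (R 4.3.3, limma 3.58.1).

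The groups, the comparisons, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. By that rule the text names, for each comparison with placebo and for tumour against liver, the 10 largest rises and 10 largest falls among genes past the limit in which every animal of the first group lay on 1 side of the mean of the second, leaving out predicted genes without a proper name. It also names list members with the lowest p, and in every comparison Afp, Gpc3, Igf2, Sqstm1, Map1lc3b, Glul, Alb, Cyp7a1, Fasn and Igfbp1, while H19 and Mki67, chosen as well, are not analysed here. Between treatments, and between the tissues, it names the 5 largest in each direction.

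The 41 gene lists held 644 genes, of which 558 had a probe and 490 were tested, covering liver functions, growth and stress pathways, handling and other cell types. A list needed 3 measured members, which left 40. Each was tested with camera (limma) at a preset correlation of 0.01, adjusted over the 40 lists of a comparison. Camera with an estimated correlation, fry for a common direction and fry for change in either direction were alternatives.

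A tumour signature score was made from the genes that differed at least 2-fold between placebo tumour and placebo liver, as the mean log2 of raised genes minus that of lowered genes, scaled to 0 in placebo liver and 1 in placebo tumour. Each placebo tumour was scored with a signature built without it, and treated animals with the mean over the 6 such signatures. Scores were compared by exact two-sided permutation tests over animals. That the adjusted p over the 3 treatments decides was settled after the raw values had been seen, so both are printed. Scores of livers, and of treatments against each other, were not planned.

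Effects of treatments against the same placebo animals share the chance values of those animals. Their covariance across genes is therefore given beside that of 100 simulations of unchanged groups, and again with the placebo animals divided, in 20 ways for tumours and 35 for livers, so that each effect used its own part. The genes shared by BEZ235 and combination livers were treated alike.

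Simulated changes in the real genes tested the procedures. For placebo tumour against liver, 59.7% of 1.5-fold, 89.6% of 2-fold and 100% of 4-fold changes were recovered, with 9 false calls. For combination tumours they were 37.3%, 71.6% and 98.5% with 11 false calls. Yet real Cyp2f2 (12.61, placebo 9.51) did not pass there, so 4-fold changes can be missed.

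Alternatives were no background correction, median scaling in place of quantile normalization, the deposited values without further normalization, no filter and a stricter filter on dim probes, the mean over the probes of a gene, 1 tumour per animal, every tumour as its own array with the animal as a random block, array weights, fits of only the groups compared, other treatments of the animal as a block, other signatures, a score baseline without the liver of the held-out animal, and leaving out each animal in turn. The number of arrays limits the precision.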

Results

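The data were 64 expression arrays from 31 mice with liver tumours induced by diethylnitrosamine. The mice had received placebo, RAD001, BEZ235 or both. RAD001 is everolimus, an allosteric inhibitor of the mTORC1 kinase complex, and BEZ235 inhibits the catalytic sites of PI3K and mTOR. There were 27 livers, 7 from placebo animals, 6 from BEZ235, 7 from RAD001 and 7 from combination animals. The 37 tumours were 10 from 6 placebo animals, 10 from 6 BEZ235 animals, 10 from 6 RAD001 animals and 7 from 4 combination animals. Values are log2 intensities, 1 per animal and tissue, with SD or SE, and all adjusted p values are from limma unless a permutation test is named.

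The first comparison asked how tumours of placebo animals differed from the liver around them. Many metabolic genes of liver were lower in tumours, and fetal and proliferative genes were higher. Ly6d, a lymphoid and progenitor surface antigen, stood at 11.65 ± 0.47 (SD, n = 6) in tumours and 6.03 ± 0.82 (n = 7) in livers, a log2 difference of 5.60 (SE 0.78, adjusted p = 1.24e-07). Gpc3, a fetal proteoglycan used as a marker of hepatocellular carcinoma, stood at 12.16 ± 1.02 against 7.18 ± 0.80 (5.01, SE 0.75, adjusted p = 4.85e-07), and Lcn2, an iron-binding acute phase protein, at 13.80 ± 0.50 against 8.97 ± 0.68 (4.83, SE 0.52, adjusted p = 4.53e-10). Cyp4a12a, a male-specific fatty acid hydroxylase, fell to 7.57 ± 1.49 from 12.96 ± 0.64 (-5.41, SE 0.80, adjusted p = 4.57e-07). Each of these was shifted in the same direction in 6 of 6 tumour animals.

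There 3651 of 10493 genes passed, 1969 higher and 1682 lower in tumours, and 1076 of them changed at least 2-fold, 578 upward and 498 downward. The largest rises, after Ly6d and Gpc3, began with Spink1, a secreted trypsin inhibitor (4.91, adjusted p = 3.43e-08), and Akr1c18, a steroid reductase (4.89, adjusted p = 2.81e-07). Lcn2, Csn3 (4.71) and Igdcc4 (4.66) came next. Cd63, a tetraspanin of lysosomes and exosomes (4.42, SE 0.33, adjusted p = 2.59e-13), Psat1, an enzyme of serine synthesis (4.41), and Kif5c (4.34) followed. The largest falls, after Cyp4a12a, were those of Cyp4a12b (-5.33), Nnmt, which methylates nicotinamide (-5.22, SE 0.63, adjusted p = 6.67e-09), Nat8 (-5.06) and Cyp2b10 (-5.04). Etnppl (-5.00), Cyp4a14 (-4.92), Hsd3b5 (-4.83), Sult2a8 (-4.69) and Ces3b (-4.61) were next. All were shifted in 6 of 6 tumour animals.

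Among the fixed lists, mitosis genes rose together, with 12 of 12 members past the limit both over all genes and adjusted over the list alone. Cenpa, a centromeric histone, rose by 2.44 (SE 0.19, adjusted p = 3.08e-13) and Birc5, the mitotic survival factor survivin, by 2.52 (adjusted p = 3.59e-11). The list stood apart by camera with an adjusted p of 5.37e-14, and with adjusted p = 0.0603 with an estimated correlation. Of 18 DNA replication genes 12 rose, 14 adjusted over the list alone, including Uhrf1 (2.61) and Tyms (0.94), with a camera adjusted p of 0.000117, against adjusted p = 0.224 with an estimated correlation. Fetal and carcinoma markers rose in 8 of 12 members by both counts, with Golm1 at 3.33 (adjusted p = 8.19e-10) and Afp, the fetal serum protein, at 3.32 (adjusted p = 2.7e-05). The camera adjusted p was 2.72e-06, adjusted p = 0.0921 with an estimated correlation.

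Of the biosynthetic and stress lists some were higher, while fatty acid synthesis, ribosome biogenesis, NRF2, p53 and hypoxia genes were not shifted (camera adjusted p from 0.169 to 0.907). Cholesterol synthesis had 11 of 17 members up and 1 down, 12 and 1 adjusted over the list alone (camera adjusted p = 0.00537, adjusted p = 0.497 with an estimated correlation). Sqle, the epoxidase of the pathway, stood 2.81 higher and Lss, the cyclase, 1.80. Of 19 genes of the unfolded protein response and ATF4, 11 rose and 1 fell, 15 and 2 adjusted over the list alone (camera adjusted p = 0.000668, adjusted p = 0.155 with an estimated correlation). Among them Xbp1 stood 1.07 higher. Ribosomal proteins rose in 9 of 11 members, 10 adjusted over the list alone (camera adjusted p = 0.000103, adjusted p = 0.211 with an estimated correlation). Rpl3 stood 0.65 higher. Rps19 stood 0.69 higher on its brightest probe and -0.24 with the mean over its probes. Immediate early genes, which respond to handling within minutes, rose in 6 of 11 members and fell in 1, 6 and 2 adjusted over the list alone (camera adjusted p = 0.0432, adjusted p = 0.444 with an estimated correlation). Egr1 (3.10) and Atf3 (2.15) led them, and the shift did not pass without placebo animal 710, 747 or 771 (adjusted p up to 0.0796).

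Cytochrome P450 and drug metabolism genes fell in 12 of 15 members and rose in 1, 12 and 2 adjusted over the list alone. Cyp2c29 (-4.18, adjusted p = 2e-12) and Cyp2f2, an enzyme of periportal hepatocytes (-4.32, adjusted p = 1.05e-11), were among them. Bile acid synthesis and transport fell in 10 of 14 members and rose in 1 by both counts. They included Cyp27a1, a sterol hydroxylase (-2.32), Slco1b2, an uptake transporter (-3.20), and Cyp7a1, the rate-limiting enzyme (-3.27, adjusted p = 0.000118). The camera adjusted p was 1.71e-11 for P450 and 2.66e-06 for bile acid genes, with adjusted p = 0.0603 and 0.0764 with an estimated correlation. Urea and amino acid metabolism fell in 14 of 17 members by both counts (camera adjusted p = 7.42e-07), with Gnmt, the glycine methyltransferase, at -2.27. Male-biased liver genes fell in 8 of 9 members and rose in 1 by both counts, with Susd4 at -3.58 and Nudt7 at -2.27 (camera adjusted p = 4.08e-07), and for these lists it was adjusted p = 0.155 and 0.0965 with an estimated correlation.

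Fatty acid oxidation fell in 11 of 15 members and rose in 1 by both counts, with Cpt2, of the mitochondrial carnitine shuttle, at -1.35 (camera adjusted p = 5e-05). Oxidative phosphorylation fell in 14 of 17, 15 adjusted over the list alone, with Ndufb5 at -0.99 and Sdhb at -0.76 (camera adjusted p = 6.77e-05), both with adjusted p = 0.177 with an estimated correlation. Gluconeogenesis and FOXO target genes fell in 6 of 11 members and rose in 1, 7 and 1 adjusted over the list alone. Pck1, the gate enzyme of gluconeogenesis, fell by 2.33 (SE 0.28, adjusted p = 4.61e-09). The gene that rose was Igfbp1, a FOXO target that binds insulin-like growth factors (3.24, adjusted p = 5.05e-06). The list had a camera adjusted p of 0.0349, adjusted p = 0.126 with an estimated correlation. Hepatocyte identity genes fell in 4 of 12 members and rose in 1, 5 and 1 adjusted over the list alone, with Hpd at -2.68 and Cebpa at -1.0 (camera adjusted p = 0.0308). Pericentral and Wnt target genes fell in 5 of 13 by both counts, with Cyp1a2 at -2.77 and Cyp2e1 at -2.13 (camera adjusted p = 0.0308). Periportal genes fell in 3 of 7 and rose in 1 by both counts (camera adjusted p = 0.0362). In this order it was adjusted p = 0.118, 0.497 and 0.343 with an estimated correlation. Without at least 1 placebo animal the hepatocyte identity, pericentral and periportal shifts did not pass (adjusted p up to 0.0953).

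Autophagy genes fell in 10 of 27 members and rose in 3 by both counts. Those that fell included Atg3, a conjugating enzyme of autophagosome formation (-1.04, adjusted p = 3.53e-08), Map1lc3a (-1.49, adjusted p = 7.03e-08) and Map1lc3b (-0.41, adjusted p = 0.0329), which did not pass without placebo animal 744, 748, 769 or 771 (adjusted p up to 0.188). Sqstm1, the cargo receptor p62, differed by 0.00 (adjusted p = 0.988). The camera adjusted p was 0.0362 (0.0574 without placebo 769), adjusted p = 0.0921 with an estimated correlation. Lysosomal genes rose in 6 of 18 and fell in 2 by both counts, with Hexa at 0.97 and Lamp2 at -0.84 (camera adjusted p = 0.559). The mTOR pathway list had 4 of 16 up and 3 down by both counts, with Deptor, an mTOR-binding inhibitor, at -0.65 (adjusted p = 0.000278) and Pik3r1 at -0.70 (camera adjusted p = 0.907).

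Markers of other cell types moved too. Macrophage markers fell in 6 of 10 members by both counts, with Cd163 at -3.26 (adjusted p = 2.11e-11) and Clec4f, of Kupffer cells, at -2.07 (camera adjusted p = 0.00062, adjusted p = 0.315 with an estimated correlation). Genes of MHC class II antigen presentation rose in 5 of 7 by both counts, with H2-Eb1 at 1.22 (adjusted p = 0.00101) and H2-Ab1 at 1.15 (camera adjusted p = 0.0432, up to 0.128 without placebo 710, 747 or 748, adjusted p = 0.497 with an estimated correlation). Stellate cell and matrix genes rose in 7 of 16 and fell in 1, 8 and 1 adjusted over the list alone (camera adjusted p = 0.084). Of the remaining fixed genes Alb rose by 0.79 (adjusted p = 0.0224) on a dim probe, while Igf2 (0.13, adjusted p = 0.912), Glul (-0.75, adjusted p = 0.073) and Fasn (-0.06, adjusted p = 0.868) did not pass. Alb was not past the limit without placebo animal 696 or 771 or with every tumour as its own array (adjusted p up to 0.0682). Glul was without placebo animal 710, 724 or 747, without background correction, with the deposited values and with 1 tumour per animal (adjusted p from 0.0176 to 0.0449). With the animal as a fixed block, in the 4 placebo animals that gave both tissues, 2247 genes passed.

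The next comparisons asked what each treatment changed in tumours. In BEZ235 tumours (n = 6 against 6) genes of glucose production and drug metabolism lay above their placebo levels. No single gene passed in limma, with 558 at an unadjusted p under 0.05 and a smallest adjusted p of 0.223. Pck1 stood at 7.18 ± 0.44 against 5.87 ± 0.55 in placebo tumours (1.31, SE 0.36, adjusted p = 0.688), above the placebo mean in 6 of 6 animals, and G6pc, the last enzyme of glucose release, differed by 1.08. Gluconeogenesis and FOXO targets were positive in 10 of 11 members, with 0 past the limit over all genes and 1 adjusted over the list alone. They were shifted upward by camera with an adjusted p of 0.000188, adjusted p = 0.0613 with an estimated correlation. The P450 list was positive in 12 of 15 members, with 0 past the limit over all genes and 4 adjusted over the list alone. Cyp2f2 stood at 12.00 ± 0.92 against 9.51 ± 1.11 (2.50, SE 0.60, adjusted p = 0.572), in 6 of 6 animals, and Cyp3a25 differed by 0.95. The camera adjusted p was 0.000188, adjusted p = 0.6 with an estimated correlation. Beside these shifts, tumours of animals 693 and 759 lay toward liver, with tumour signature scores of 0.312 and 0.702 (placebo tumour 1) and fitted liver shares of 65.2% and 24.3% in an assumed linear mixture, against 0 to 9% in placebo tumours. Both lists passed with 693 or 759 left out alone, in fits chosen after the data were seen. No fit left out both animals, and fry gave 0 lists in any treated tumours.

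Further lists were shifted upward by camera in BEZ235 tumours. Periportal genes were positive in 6 of 7 members, with 1 adjusted over the list alone and Gldc at 0.92 (adjusted p = 0.00484, adjusted p = 0.477 with an estimated correlation). Urea and amino acid metabolism was positive in 12 of 17, with Gnmt at 0.99 and Arg1 at 0.72 (adjusted p = 0.00837). Bile acid genes were positive in 11 of 14, with Cyp8b1 at 2.18 and Baat at 0.86 (adjusted p = 0.0188), and male-biased genes in 7 of 9 (adjusted p = 0.0104). Fatty acid oxidation was positive in 12 of 15, with Acot1 at 1.60 and Angptl4 at 0.73 (adjusted p = 0.0323). NRF2 targets of the oxidative stress response were positive in 13 of 15, with Gclc at 0.47 and Gclm at 0.43 (adjusted p = 0.0323). Pericentral and Wnt target genes were shifted downward, with 3 of 13 positive, Rhbg at -1.19 and Rnf43 at -0.35 (adjusted p = 0.014). From urea metabolism on, each list had 0 members adjusted over the list alone and adjusted p = 0.817 with an estimated correlation. Autophagy (Atg2a 0.53, Gabarapl2 -0.35, adjusted p = 0.974), lysosome (adjusted p = 0.197), mTOR pathway (adjusted p = 0.974) and mitosis genes (adjusted p = 0.552) were not shifted by camera. Of the fixed genes Afp differed by -0.88, Gpc3 by -1.51, Igf2 by 0.38, Sqstm1 by 0.22, Map1lc3b by 0.18, Glul by -0.44, Alb by -0.11, Cyp7a1 by 0.95, Fasn by -0.06 and Igfbp1 by -0.37, and 0 of these passed. Without 1 animal the calls of fatty acid oxidation ended in 5 of 12 fits (adjusted p up to 0.371), of bile acid genes in 3 (0.246), of urea metabolism in 3 (0.0955) and of male-biased genes in 1 (0.141), each highest without 693. Those of NRF2 targets ended in 5 (0.297, without placebo 696) and of pericentral genes in 4 (0.285, without placebo 710). Without placebo animal 748, 2 genes passed, and with every tumour as its own array 1 did.

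In RAD001 tumours (n = 6 against 6) genes of the respiratory chain lay above, and fetal and carcinoma markers below, their placebo levels. Again 0 genes passed in limma, with 740 at an unadjusted p under 0.05 and a smallest adjusted p of 0.327. All 17 oxidative phosphorylation genes were positive, with Cycs, cytochrome c, at 0.44 and Uqcrc2, of complex III, at 0.38, and 0 adjusted over the list alone. The list was shifted upward by camera with an adjusted p of 0.000112, and with adjusted p = 0.847 with an estimated correlation. Gpc3 stood at 9.07 ± 2.52 against 12.16 ± 1.02 (-3.09, SE 1.02, adjusted p = 0.63), below the placebo mean in 6 of 6 animals, and Akr1c18 differed by -2.46 (SE 0.82). Of the 12 fetal and carcinoma markers 2 were positive, 2 passed adjusted over the list alone and 0 over all genes. Camera gave a downward shift with an adjusted p of 0.00833, adjusted p = 0.847 with an estimated correlation. Gluconeogenesis and FOXO targets were positive in 10 of 11, with 1 adjusted over the list alone, Pck1 at 1.22 (SE 0.36, 5 of 6 animals) and G6pc at 1.03 (adjusted p = 0.00833, adjusted p = 0.371 with an estimated correlation). Tumours of animals 732 and 730 lay toward liver, at scores of 0.472 and 0.590 with fitted liver shares of 38.8% and 33%. The 3 lists passed without either.

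Urea and amino acid metabolism was shifted upward in RAD001 tumours, with 12 of 17 positive, Bhmt at 1.13 and Gnmt at 1.04 (adjusted p = 0.0233). So was fatty acid oxidation, with 13 of 15 positive, Acadm at 0.40 and Angptl4 at 0.56 (adjusted p = 0.0255). Pericentral and Wnt target genes were shifted downward, with 1 of 13 positive, Lgr5, a Wnt-induced receptor, at -0.54 and Rnf43 at -0.32 (adjusted p = 0.0255). Each of the 3 lists had 0 members adjusted over the list alone and adjusted p = 0.949 with an estimated correlation. Autophagy (Map1lc3a 0.54, Atg7 0.32, adjusted p = 0.604), lysosome (adjusted p = 0.431) and mTOR pathway genes (Ddit4 1.01, Akt1s1 0.36, adjusted p = 0.256) were not shifted. Of the other fixed genes Afp differed by -1.32, Igf2 by 0.34, Sqstm1 by 0.39, Map1lc3b by 0.22, Glul by -0.26, Alb by -0.40, Cyp7a1 by 0.70, Fasn by 0.08 and Igfbp1 by -1.27, and 0 of these passed. Without 1 animal the calls of pericentral genes ended in 7 of 12 fits (adjusted p up to 0.396, without placebo 710), of fatty acid oxidation in 6 (0.236, without 763) and of urea metabolism in 4 (0.537, without 732). Without 730 or placebo 747, 3 lists passed. Without RAD001 animal 727, and with array weights, 2 genes passed.

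In combination tumours (n = 4 against 6) genes of cell division and of the interferon response lay below, and several metabolic lists above, their placebo levels. No gene passed in limma, with 839 at an unadjusted p under 0.05 and a smallest adjusted p of 0.158. None of the 12 mitosis genes was positive. Cenpa stood at 9.86 ± 0.60 against 10.52 ± 0.17 (-0.66, SE 0.22, adjusted p = 0.487), below the placebo mean in 3 of 4 animals, and Bub1b, of the spindle checkpoint, differed by -0.44. The list was shifted downward by camera with an adjusted p of 3.49e-06, adjusted p = 0.411 with an estimated correlation. DNA replication genes were shifted downward too, with 2 of 18 positive, Cdc6 at -0.64 and Mcm2 at -0.55 (adjusted p = 0.0106, adjusted p = 0.527 with an estimated correlation). Both lists had 0 members adjusted over the list alone. Of 15 interferon response genes 0 were positive and 1 passed adjusted over the list alone. It was Tap1, the peptide transporter of antigen presentation, at -1.02 (SE 0.22, adjusted p = 0.214, 4 of 4 animals), with Isg15 at -1.22. The camera adjusted p was 0.000112, adjusted p = 0.527 with an estimated correlation. Beside it T and NK cell markers were shifted downward, with 1 of 8 positive, Cd8b1 at -0.90 and Cd3e at -0.66 (adjusted p = 0.0328). Stellate cell and matrix genes were as well, with 2 of 16 positive, Reln at -1.41 and Col1a2 at -0.29 (adjusted p = 0.028). For both it was adjusted p = 0.527 with an estimated correlation, with 0 members adjusted over the list alone. The tumour of animal 773 lay toward liver, at a score of 0.402 with a fitted liver share of 58%. Without 1 animal the call of matrix genes ended in 4 of 10 fits (adjusted p up to 0.147 without placebo 747, and 0.0505 without 773), of T and NK cell markers in 4 (0.233, without placebo 747), of DNA replication in 3 (0.277, without placebo 769), and of mitosis and interferon genes in 0.

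The P450 list was shifted upward in combination tumours, with 12 of 15 positive and 1 adjusted over the list alone, Cyp2f2, at 12.61 ± 1.32 against 9.51 ± 1.11 (3.10, SE 0.67, adjusted p = 0.214, 4 of 4 animals). Its camera adjusted p was 0.000112, adjusted p = 0.411 with an estimated correlation. Periportal genes were positive in 6 of 7 members with 1 adjusted over the list alone (adjusted p = 0.00667). Gluconeogenesis and FOXO targets were positive in 9 of 11 with 0 adjusted over the list alone, Pck1 at 1.10 and Irs2 at 0.70 (adjusted p = 0.028). Both had adjusted p = 0.411 with an estimated correlation. Oxidative phosphorylation was positive in 16 of 17 members, with Ndufb5 at 0.44 and Uqcrc2 at 0.32 (adjusted p = 0.000533). Fatty acid oxidation was positive in 14 of 15, with Pdk4 at 0.89 and Angptl4 at 0.88 (adjusted p = 0.00667). NRF2 targets were positive in 12 of 15, with Gclc at 0.78 and Gclm at 0.65 (adjusted p = 0.00786). Fetal and carcinoma markers were shifted downward, with 2 of 12 positive, Ly6d at -1.74 and Lcn2 at -1.31 (adjusted p = 0.0154). Pericentral and Wnt target genes were as well, with 2 of 13 positive, Rhbg at -1.48 and Lgr5 at -0.67 (adjusted p = 0.0149). These 5 lists had adjusted p = 0.527 with an estimated correlation. Bile acid genes were positive in 9 of 14, with Cyp8b1 at 2.67 and Slc10a1 at 0.70 (adjusted p = 0.00667, adjusted p = 0.516 with an estimated correlation). These last 6 lists had 0 members adjusted over the list alone. Autophagy (Gabarapl1 0.88, Atg2a 0.52, adjusted p = 0.378), lysosome (adjusted p = 0.235) and mTOR pathway genes (adjusted p = 0.378) were not shifted. Of the fixed genes Afp differed by -1.21, Gpc3 by -1.55, Igf2 by -0.98, Sqstm1 by 0.36, Map1lc3b by 0.09, Glul by -0.54, Alb by 0.01, Cyp7a1 by 2.11 (adjusted p = 0.607), Fasn by 0.31 and Igfbp1 by -0.80. Without animal 773 the calls of NRF2 targets (adjusted p = 0.716), fetal markers (0.185), bile acid genes (0.182), fatty acid oxidation and oxidative phosphorylation (0.0505 for both) ended. Of the 10 fits without 1 animal, 5 ended that of pericentral genes (up to 0.232, without placebo 710), 4 that of gluconeogenesis (0.284, without 726), and 0 those of P450 and periportal genes. With every tumour as its own array 10 genes passed, Tap1 among them (adjusted p = 0.0388).

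The tumour signature score set liver at 0 and placebo tumour at 1. Placebo tumours scored 1 ± 0.102 (SD, n = 6). BEZ235 tumours scored 0.803 ± 0.268 (n = 6), lower by an exact two-sided permutation p of 0.104 (adjusted 0.104), with 5 of 6 animals below the placebo mean. RAD001 tumours scored 0.769 ± 0.220 (n = 6, 5 of 6 below), with an exact permutation p of 0.0433 (adjusted 0.0649). Combination tumours scored 0.752 ± 0.235 (n = 4, 4 of 4 below), with an exact permutation p of 0.0190 (adjusted 0.0571). After adjustment over the 3 treatments 0 passed. The combination crossed the limit (adjusted exact permutation p = 0.0429) with the signature of the 100 largest rises and falls, without background correction and with the deposited values. So did each treatment in 1 fit without 1 animal. The adjusted exact permutation p was 0.0357 for BEZ235 without 728, 0.0195 for RAD001 without 727 and 0.0238 for the combination without placebo 710. Other such fits gave up to 0.208, 0.130 and 0.102. No difference between treatments passed (adjusted exact permutation p = 0.895 for each). Without 693 the difference of BEZ235 was -0.0989, and without 773 that of the combination -0.130.

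**Figure D1:**
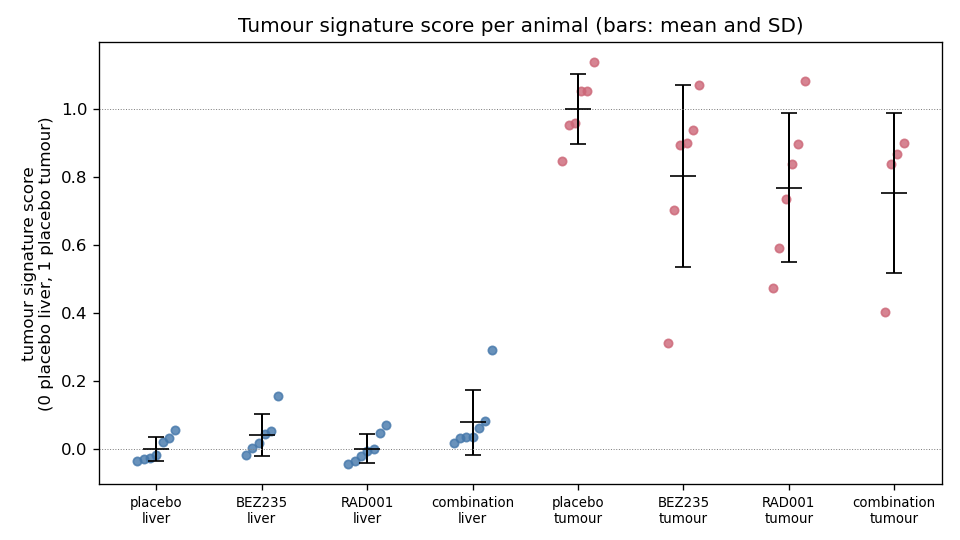
Tumour signature score on the vertical axis (no unit) by treatment and tissue. Each point is 1 animal, and the bars are the mean and SD. Placebo tumours lay between 0.847 and 1.14, BEZ235 tumours between 0.312 and 1.07, RAD001 tumours between 0.472 and 1.08 and combination tumours between 0.402 and 0.901.

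In liver the treatments changed few genes, and BEZ235 (n = 6 against 7) changed 3. Depp1, a FOXO target induced by fasting, rose from 9.80 ± 0.65 to 11.75 ± 0.53 (1.94, SE 0.31, adjusted p = 0.00893), and Ccn2, a matricellular growth factor, from 9.25 ± 0.47 to 10.61 ± 0.21 (1.37, SE 0.24, adjusted p = 0.0226). Klf2, a zinc finger transcription factor, fell from 7.41 ± 0.57 to 6.18 ± 0.32 (-1.23, SE 0.23, adjusted p = 0.0263), all in 6 of 6 animals, and 541 genes had an unadjusted p under 0.05. Fatty acid oxidation genes were shifted upward by camera (13 of 15 positive, adjusted p = 0.000693, adjusted p = 0.811 with an estimated correlation), with 0 past the limit over all genes and 2 adjusted over the list alone. Pdk4, which limits glucose oxidation, stood at 8.54 ± 0.83 against 6.90 ± 0.73 (1.64, adjusted p = 0.269, 6 of 6 animals). Autophagy (Atg3 -0.27, Sqstm1 0.20, adjusted p = 0.89), lysosome (adjusted p = 0.66) and mTOR pathway genes (adjusted p = 0.765) were not shifted. Of the other fixed genes Afp differed by -0.13, Gpc3 by 0.04, Igf2 by -0.83, Map1lc3b by -0.22, Glul by -0.16, Alb by 0.26, Cyp7a1 by -0.12, Fasn by -0.30 and Igfbp1 by 1.0, and 0 of these passed. Without BEZ235 animal 693 or 759 no gene passed, and without BEZ235 animal 697 or 725, or placebo animal 724 or 776, 1 did. The calls of Klf2 (adjusted p up to 0.154) and Ccn2 (up to 0.0944) each ended in 8 of 13 fits without 1 animal, that of Depp1 in 2 (up to 0.0567), and that of Klf2 also without the filter (0.0543) and with array weights (0.0536). Up to 6 lists passed, without placebo 710 or BEZ235 755.

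In RAD001 livers (n = 7 against 7) proliferation and plasma cell genes lay below placebo levels. No gene passed in limma, with 674 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0738. DNA replication genes were shifted downward, with 2 of 18 positive, Mcm5 at -0.68 and Mcm2 at -0.67 (camera adjusted p = 0.00143). Mitosis genes were as well, with 1 of 12 positive, Cdc20 at -0.74 and Cdk1 at -0.60 (adjusted p = 0.00502). For these it was adjusted p = 0.142 and 0.402 with an estimated correlation, with 2 members each adjusted over the list alone and 0 over all genes. B and plasma cell markers were shifted downward, with 1 of 5 positive and 1 adjusted over the list alone (adjusted p = 0.00148, adjusted p = 0.109 with an estimated correlation). Mzb1 stood at 4.57 ± 0.29 against 5.58 ± 0.72 (-1.02, SE 0.23, adjusted p = 0.184, 7 of 7 animals). Mzb1, Mcm2 (4.78) and Plk1 (4.58) lay near background, and Mcm5 (5.81) above it. Macrophage markers were shifted downward too, with 1 of 10 positive, Marco at -0.80 and Adgre1 at -0.58 (adjusted p = 0.0269, adjusted p = 0.845 with an estimated correlation).

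Fatty acid oxidation was shifted upward in RAD001 livers, with 13 of 15 positive, Cyp4a14 at 0.59 and Slc25a20 at 0.25 (adjusted p = 0.00101). Ribosomal proteins were as well, with 11 of 11 positive, Rps3 at 0.20 and Rps15 at 0.19 (adjusted p = 0.00502). Lysosomal genes were shifted downward, with 4 of 18 positive, Hexa at -0.25 and Naglu at -0.21 (adjusted p = 0.0269). P450 genes were positive in 5 of 15, with Cyp2b10 at -0.89 and Cyp2a5 at -0.45 (downward adjusted p = 0.0269). Urea and amino acid genes were positive in 6 of 17, with Agxt at -0.51 and Hpd at -0.32 (downward adjusted p = 0.0261). In this order it was adjusted p = 0.351, 0.402, 0.109, 0.402 and 0.762 with an estimated correlation. These 5 lists and the macrophage markers had 0 members adjusted over the list alone. With median scaling the lysosomal (adjusted p = 0.277), urea and P450 (adjusted p = 0.195 for both) and macrophage shifts (adjusted p = 0.0621) did not pass. Each of these also did not pass without at least 1 animal, with an adjusted p of up to 0.639 for urea genes without RAD001 732. Autophagy (Atg4b 0.43, Ulk1 0.23, adjusted p = 0.723) and mTOR pathway genes (adjusted p = 0.73) were not shifted. Of the fixed genes Afp differed by 0.17, Gpc3 by -0.81, Igf2 by -0.56, Sqstm1 by 0.04, Map1lc3b by -0.10, Glul by -0.29, Alb by 0.20, Cyp7a1 by 0.01, Fasn by 0.07 and Igfbp1 by 0.36. Without RAD001 animal 730, and with array weights, 1 gene passed.

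The combination changed 29 genes in liver (n = 7 against 7), 19 upward and 10 downward, 10 of them at least 2-fold, while 886 had an unadjusted p under 0.05. Depp1 rose from 9.80 ± 0.65 to 11.96 ± 0.32 (2.15, SE 0.30, adjusted p = 0.000472). Efna1, a membrane-bound ephrin ligand, rose from 7.95 ± 0.19 to 9.56 ± 0.58 (1.61, SE 0.24, adjusted p = 0.000735), and Klf6, a zinc finger transcription factor, from 7.07 to 8.50 (1.43, SE 0.20, adjusted p = 0.000472). Ccn2 (1.38, adjusted p = 0.00337), Serpina7, which carries thyroxine in blood (1.22, adjusted p = 0.00478), and Osgin1, an NRF2-regulated stress gene (1.18, adjusted p = 0.0147), also rose. Further rises were those of Irs2, the insulin receptor substrate that FOXO induces (1.18, adjusted p = 0.0125), Dusp6, a phosphatase of ERK (0.93, adjusted p = 0.0361), Mgst3 (0.85, adjusted p = 0.0382) and Tgif1 (0.75, adjusted p = 0.0184). Cabyr (-1.59, adjusted p = 0.00337), Klf2 (-1.36, SE 0.22, adjusted p = 0.00211), Cox8b (-1.08, adjusted p = 0.0456), Enpp6 (-0.97, adjusted p = 0.0146) and Sertad1 (-0.94, adjusted p = 0.0382) fell. So did Frat2 (-0.94, adjusted p = 0.0382), Adam23 (-0.73, adjusted p = 0.0146), Csrnp1 (-0.71, adjusted p = 0.0398), Enpp5 (-0.57, adjusted p = 0.044) and Fbxo33 (-0.50, adjusted p = 0.0398). Each of these 20 genes was shifted in 7 of 7 animals. The liver of animal 742 lay toward tumour (score 0.290, fitted tumour share 19.7%), and without it 21 genes passed.

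Interferon response genes were shifted downward in combination livers, with 0 of 15 positive and 2 adjusted over the list alone (camera adjusted p = 2.84e-06, adjusted p = 0.293 with an estimated correlation). Cxcl9, a chemokine for T cells, stood at 8.35 ± 0.53 against 9.36 ± 0.56 (-1.01, adjusted p = 0.174, 7 of 7 animals) and Psmb9 differed by -0.62. Beside them T and NK cell markers were shifted downward, with 2 of 8 positive, 2 adjusted over the list alone, Ccl5 at -0.91 and Cd8b1 at -0.61 (adjusted p = 0.0379). MHC class II genes were as well, with 1 of 7 positive, 1 adjusted over the list alone, H2-Eb1 at -0.46 and H2-Aa at -0.42 (adjusted p = 0.0351). Neutrophil markers were shifted upward, with 6 of 6 positive, 1 adjusted over the list alone, S100a9 at 0.78 and Camp at 0.57 (adjusted p = 0.00458). Immediate early genes were positive in 9 of 11, with 2 up and 1 down adjusted over the list alone, Ier3 at 1.03 and Junb at 0.85 (upward adjusted p = 0.0258). For these 4 lists, in this order, it was adjusted p = 0.293, 0.424, 0.072 and 0.397 with an estimated correlation. Without animal 742 the immediate early shift did not pass (adjusted p = 0.0773) and those of the other 9 lists of these livers did. Without the filter on dim probes the T and NK cell (adjusted p = 0.111) and MHC class II shifts (adjusted p = 0.0848) did not pass.

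Gluconeogenesis and FOXO targets were shifted upward in combination livers, with 7 of 11 positive, Irs2 past the limit over all genes, 4 genes adjusted over the list alone, and Ppargc1a at 0.60 (adjusted p = 0.00458, adjusted p = 0.072 with an estimated correlation). The 4 negative members, looked up after the result was seen, were Klf15 (-0.23), Sesn3 (-0.18), Sesn1 (-0.061) and Pck1 (-0.040). Fatty acid oxidation was positive in 13 of 15, with 1 adjusted over the list alone and Acadl at 0.35 (upward adjusted p = 7.18e-05, adjusted p = 0.293 with an estimated correlation). Pdk4 stood at 8.62 ± 0.90 against 6.90 ± 0.73 (1.71, SE 0.40, adjusted p = 0.0594, 6 of 7 animals) and crossed the limit with median scaling, the stricter filter, array weights and without combination 713 or placebo 724 (adjusted p from 0.0109 to 0.0489). Ribosomal proteins were positive in 10 of 11, with 0 adjusted over the list alone and Rps9 at 0.26 (upward adjusted p = 0.00458, adjusted p = 0.305 with an estimated correlation). Male-biased genes were shifted downward, with 0 of 9 positive, 3 adjusted over the list alone, Mup20 at -0.97 and Cyp7b1 at -0.57 (adjusted p = 5.17e-05). Periportal genes were as well, with 1 of 7 positive, 2 adjusted over the list alone, Etnppl at -0.58 and Aldh1b1 at -0.52 (adjusted p = 0.011). For both it was adjusted p = 0.293 with an estimated correlation. Autophagy (Atg2a 0.21, Ulk2 -0.20, adjusted p = 0.538), lysosome (adjusted p = 0.142) and mTOR pathway genes (adjusted p = 0.723) were not shifted. Igfbp1 stood at 7.80 ± 1.17 against 6.23 ± 0.91 (1.56, SE 0.48, adjusted p = 0.211, 6 of 7 animals). Afp differed by 0.70, Gpc3 by 0.60, Igf2 by -0.76, Sqstm1 by 0.09, Map1lc3b by -0.06, Glul by 0.15, Alb by 0.46, Cyp7a1 by 0.58 and Fasn by -0.18. The count of 29 genes was 16 without background correction and 19 in a fit of only these groups. It was 14 without combination animal 726, 15 without placebo 771, 16 without combination 764, 18 without placebo 696 and 19 without placebo 748. Among the named genes Tgif1, Dusp6, Mgst3, Cox8b, Sertad1, Frat2, Csrnp1, Enpp5 and Fbxo33 did not pass without at least 1 animal, with an adjusted p of up to 0.116 for Enpp5 without combination 726. The last 7 of these also lost their calls in at least 1 refit with other processing (adjusted p 0.0511 to 0.0806). With the mean over probes Adam23 (-0.31, adjusted p = 0.324) and Dusp6 (0.72, adjusted p = 0.1001) did not pass. Among the lists MHC class II, T and NK cell, immediate early and ribosomal genes did not pass without at least 1 animal (adjusted p up to 0.178), and 17 lists passed without combination 709, against 10.

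**Figure D2:**
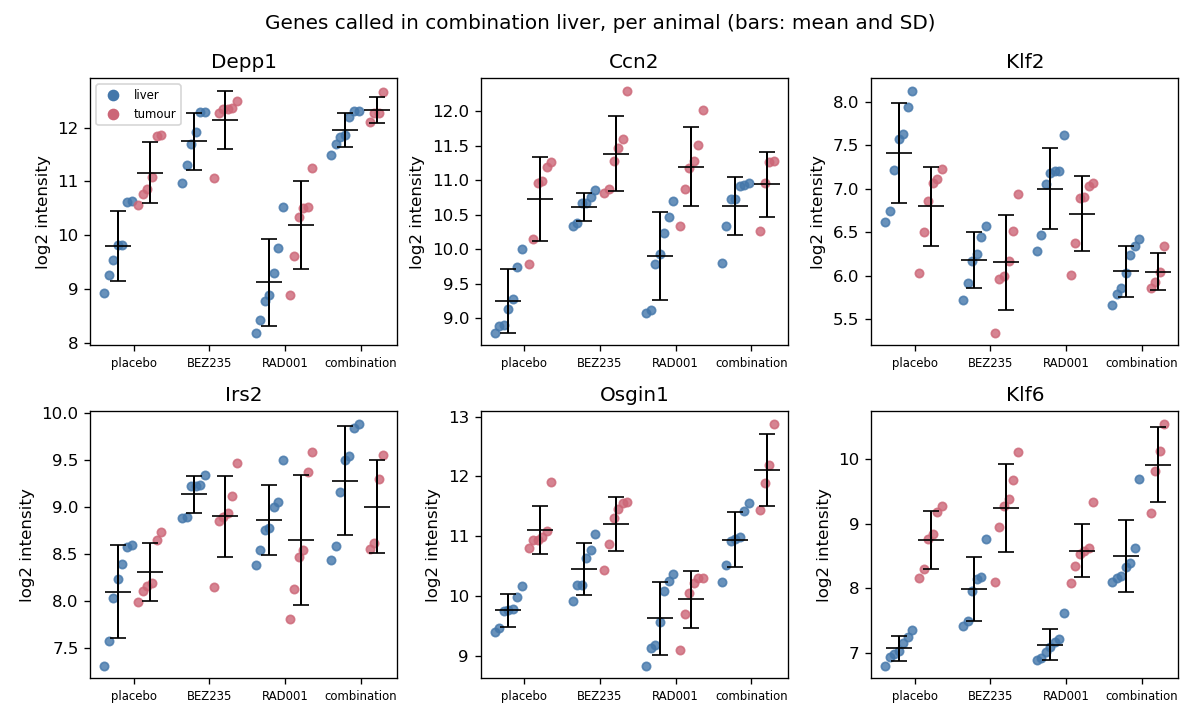
Log2 intensity on the vertical axis of Depp1, Ccn2, Klf2, Irs2, Osgin1 and Klf6, 1 panel per gene, by treatment in liver and tumour. Each point is 1 animal, and the bars are the mean and SD. Depp1 in liver stood at 9.80 in placebo, 11.75 in BEZ235, 9.12 in RAD001 and 11.96 in combination animals.

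The treatments were then compared with each other, at doses that differ between the combination and the single agents. Depp1 lay above RAD001 in tumours of BEZ235 and of the combination, and Osgin1 in those of the combination. Osgin1 stood at 12.11 ± 0.61 (n = 4) in the combination and 9.94 ± 0.47 (n = 6) in RAD001 (2.16, SE 0.29, adjusted p = 0.00196), and Depp1 at 12.32 ± 0.23 against 10.19 ± 0.82 (2.14, SE 0.36, adjusted p = 0.0348), both in 4 of 4 animals. BEZ235 tumours had Depp1 at 12.15 ± 0.54 (n = 6), 1.96 above RAD001 (SE 0.32, adjusted p = 0.0491, 6 of 6 animals). No other gene passed in these comparisons, with 481 and 402 at an unadjusted p under 0.05, and 0 passed in limma between the combination and BEZ235, with 300. With 1 tumour per animal Osgin1 no longer passed (adjusted p = 0.0588), and the Depp1 calls ended without the filter (adjusted p = 0.0786 and 0.13), that against BEZ235 also with median scaling, the deposited values and the mean over probes (up to 0.101). Without 1 animal the Depp1 call ended in 8 of 10 fits against the combination (adjusted p up to 0.245) and in 10 of 12 against BEZ235 (up to 0.229).

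In livers 92 genes differed between the combination and RAD001, 54 higher and 38 lower in the combination, with 1027 at an unadjusted p under 0.05. Higher were Depp1 (2.84, adjusted p = 2.6e-06), Cyp2b10, an inducible drug-metabolising enzyme (2.16, adjusted p = 0.000694), the chemokine Cxcl1 (2.14, adjusted p = 0.031), Efna1 (1.62, adjusted p = 0.00051) and Klf6 (1.37, adjusted p = 0.00051). Lower were Frat2 (-1.51, adjusted p = 0.000191), Cabyr (-1.38, adjusted p = 0.00677), Gdf9 (-1.28, adjusted p = 0.031), Sertad1 (-1.27, adjusted p = 0.00133) and Hexim1 (-1.12, adjusted p = 0.00361), in 7 of 7 animals each. BEZ235 and RAD001 livers differed in 16 genes, 11 higher in BEZ235 and 5 lower, with 901 at an unadjusted p under 0.05. Higher in BEZ235 were Depp1 (2.62, adjusted p = 3.15e-05), Cyp2b10 (1.70, adjusted p = 0.0282), Gsta1, a glutathione transferase (1.65, adjusted p = 0.0378), Cyp2c55 (1.49) and Uap1l1 (1.33, adjusted p = 0.0109). Lower were Sertad1 (-1.14, adjusted p = 0.0161), Frat2 (-1.09, adjusted p = 0.0203), Fbxo33 (-0.59), Fzd7 (-0.55) and Il1rap (-0.44), in 6 of 6 animals. Between the combination and BEZ235, 0 liver genes passed in limma, with 409 at an unadjusted p under 0.05 and a smallest adjusted p of 0.922. The count of 92 was 46 in a fit of only these groups, 47 without RAD001 animal 760, 51 without combination 742, 59 without RAD001 730 or 763, and 61 without RAD001 700 or combination 713. That of 16 was 6 without BEZ235 693, 7 without BEZ235 759, 8 without RAD001 760, 9 without BEZ235 712, 10 without RAD001 763 and 42 with array weights. Of the named genes, Cxcl1 and Gdf9 against the combination (adjusted p up to 0.0883), and Cyp2b10, Gsta1, Cyp2c55, Frat2, Fbxo33, Fzd7 and Il1rap against BEZ235 (adjusted p up to 0.103), did not pass without at least 1 animal. Cxcl1, Gdf9, Cyp2b10, Gsta1 and Cyp2c55 did not without the filter (adjusted p 0.0502 to 0.0599), and with the mean over probes Il1rap (-0.27, adjusted p = 0.389) and Cyp2b10 (1.14, adjusted p = 0.0555) did not.

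RAD001 effects on Hamp2, a hepcidin gene, and Igf1, a growth factor, differed between tumour and liver. Hamp2 stood at 9.33 ± 1.82 in RAD001 and 7.10 ± 1.07 in placebo tumours, and at 8.65 ± 0.74 in RAD001 and 10.41 ± 0.78 in placebo livers (difference of effects 4.0, SE 0.79, adjusted p = 0.0395). Igf1 stood at 11.16 ± 1.17 against 8.90 ± 0.78 in tumours, while livers stood at 12.41 ± 0.35 and 12.48 ± 0.18 (2.37, SE 0.43, adjusted p = 0.0184). Cyp2f2 differed in its response to the combination, at 12.61 ± 1.32 against 9.51 ± 1.11 in tumours and 13.59 ± 0.29 against 13.82 ± 0.12 in livers (3.33, SE 0.59, adjusted p = 0.0102), and stood higher in tumours in 4 of 4 animals. Genes with an unadjusted p under 0.05 numbered 787 for RAD001, 886 for the combination and 562 for BEZ235, where 0 passed. All 3 calls ended with 1 tumour per animal (adjusted p = 0.807, 0.803 and 0.0776) and with every tumour as its own array (0.735, 0.61 and 0.189), and that of Cyp2f2 without combination animal 773 (2.78, adjusted p = 0.156). Without the filter Hamp2 (adjusted p = 0.106) and Igf1 (0.0516) did not pass, nor Hamp2 with the deposited values (0.0547). With no block 1 gene passed for RAD001. Igf1 did not pass without RAD001 730 or 732 or placebo 710 or 771 (adjusted p up to 0.176), and Hamp2 did not in 10 of 17 fits without 1 animal (up to 0.196, without RAD001 700). In tumours Igf1 and Cyp2f2 moved toward liver, and Hamp2 past RAD001 livers within its SD. Surrounding liver stays open (fitted share 33% to 58% in 730, 732 and 773).

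Treatment effects were set against each other across all genes. The covariance of the log2 effects of BEZ235 and RAD001 in tumours was 0.0523, against 0.0275 from simulated unchanged groups that share the placebo animals, and 0.0291 with the placebo animals divided. For BEZ235 and the combination it was 0.0606, against 0.0277 simulated and 0.0375 divided, and for RAD001 and the combination 0.0615, against 0.0276 and 0.0383. Covariances are taken across genes, which are not independent replicates. Each effect ran against the difference of placebo tumour from liver, with covariances of -0.117, -0.134 and -0.143 for BEZ235, RAD001 and the combination, against -0.0276, -0.0278 and -0.0279 simulated and -0.0938, -0.111 and -0.120 divided. Tumours of 693, 732 and 773 lay toward liver. The divided covariance was 0.0191 for BEZ235 and RAD001 without 693, and 0.0215 and 0.0166 for the pairs with the combination without 773. In livers the covariances were 0.0120, 0.0223 and 0.0146 for the same pairs, against 0.0143, 0.0142 and 0.0143 simulated and -0.000929, 0.00936 and 0.00171 divided. Of the 3 genes that BEZ235 changed in liver, the combination changed the same 2 upward and the same 1 downward, where independent lists would share 0.00362 and 0.000953 genes. Both lists rest on the same placebo livers. That 100 simulations of unchanged groups gave 0 shared genes decides nothing, since with no gene changed few are called. With the placebo livers divided in 35 ways, BEZ235 changed a mean of 0.8286 and the combination of 9 genes. Then 1 gene was shared upward in 8 divisions and 0 in the others, and 0 downward in all 35.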

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

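Of the tests in this part, both mixing tests, the refit on ranks and all splits of the samples were chosen only after the results they bear on had been seen. The score on ranks and the comparison of dose times were set beforehand, as were first forms of the mixing tests, dropped because they ignored gaps that placebo tumours and other livers had too.

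Tumours of the 3 treatments scored nearer to liver than placebo tumours, though 0 differences passed after adjustment over the treatments. On the ranks of probes within each array, meant as a test of the authors' separate normalization of each treatment, the combination differed by -0.242 (exact permutation p = 0.0143, adjusted 0.0429), which decides nothing, since the joint normalization had already put the same values on all 64 arrays in the order of their own probes, and effects of forcing all arrays to 1 distribution stay open. Surrounding liver in the tumour samples stays open: with its share set on tumour-lowered genes, tumour-raised genes lay below the linear mixture by -0.24 (SD 0.153) in 16 of 16 treated animals, against -0.10 (SD 0.151) in held-out placebo tumours, a difference of -0.135 that rests on an assumed profile. A loss of tumour transcripts under treatment may add to the shift and is a hypothesis that these tests leave open.

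The combination changed 29 genes in liver. With every array reduced to ranks 19 of the 29 were called again, among 20 called in all, which for the same reason decides nothing on the authors' normalization. The time between last dose and sampling stays open, because BEZ235 was last given 1 h before sacrifice in every animal that received it and 0 animals were sampled at another time, so that timing and compound cannot be told apart. A response of hepatocytes to the compounds stays open as well and was not tested.

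The combination liver of animal 742 scored 0.290, the highest of its group by 0.757 of the range, against 0.0162 to 0.0827 in the others. Tumour tissue in that sample stays open. With a tumour share of 19.7% set on tumour-raised genes, tumour-lowered genes differed by -0.37 where -0.19 was predicted, and that gap exceeded the mean gap of the other combination livers by -0.104 (their SD 0.031), again on an assumed profile. No biological explanation was tested, and without this liver 21 genes passed in combination liver.

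Other animals stood apart from their group, by a gap to the nearest animal given as a share of the group's range. This held in 47 of 490 groups of values, where chance gives about 1 in 20 groups. The combination tumour of 773 was lowest in score (0.873) and highest in Gclc (0.961) and Cyp2f2 (0.941). In placebo livers 748 was highest in Csn3 (0.689), Kif5c (0.605), Afp (0.589) and Igf2 (0.634), 710 was lowest in Ces3b (0.687), Cyp27a1 (0.725), Susd4 (0.811), Angptl4 (0.640) and Mup20 (0.644), and 724 was lowest in Enpp5 (0.569). In placebo tumours 710 was lowest in Cd63 (0.646) and Cyp2f2 (0.653) and highest in Pik3r1 (0.670), Acot1 (0.700) and Acadm (0.665), and 771 was lowest in Lamp2 (0.764). In BEZ235 tumours 693 was lowest in Gldc (0.718) and Gpc3 (0.6251) and highest in Susd4 (0.756) and Elovl3 (0.676), and 755 was lowest in Depp1 (0.840). The RAD001 tumour of 763 was highest in Lgr5 (0.910) and Glul (0.826). In BEZ235 livers 755 was lowest in Atg3 (0.724), 697 highest in Map1lc3b (0.859), 759 highest in Uap1l1 (0.646) and 725 lowest in Sertad1 (0.729). In RAD001 livers 732 was lowest in Mcm5 (0.603), Hpd (0.842) and Igf1 (0.757) and highest in Cyp4a14 (0.647) and Cyp2a5 (0.586). There 760 was highest in Mzb1 (0.610), 763 lowest in Atg4b (0.613), 745 highest in Afp (0.673) and 700 lowest in Glul (0.762). In combination livers 742 was highest in Klf6 (0.664), Ier3 (0.789), Afp (0.718) and Glul (0.733), 773 in Etnppl (0.730) and Cyp2f2 (0.692), and 713 in Igf2 (0.727).

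Tumour and liver effects differed for Hamp2 and Igf1 (RAD001, 4.0 and 2.37) and Cyp2f2 (combination, 3.33). No call held with every tumour as its own array.

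Each count of genes was set against 100 splits of the same animals into groups of the same sizes, the real one included. Uncorrected over the comparisons, such counts do not exclude chance. At most 4 splits gave as many genes for tumour against liver (1 split, 3651 genes, highest other 3054). In livers the same held for BEZ235 (1 split, 3 genes against 2) and the combination (1 split, 29 against 2). Against RAD001 livers it held for the combination (1 split, 92 against 29) and BEZ235 (1 split, 16 against 1). It also held for the tissue difference of RAD001 (1 split, 2 against 1). For BEZ235 and the combination against RAD001 tumours it held at 4 splits each. Other splits gave up to 2 genes against 1, and up to 43 against 2. The cause was not tested, and the call against BEZ235 ended in 10 of 12 fits without 1 animal. The tissue difference of the combination did not stand out (15 splits, 1 against 4). Where 0 genes passed, all 100 splits gave as many, with a highest other of 1 for BEZ235 tumours, 4 for RAD001 and for combination tumours, 1 for RAD001 livers, 1 and 6 for the combination against BEZ235 in tumours and livers, and 2 for the tissue difference of BEZ235.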

How the results depend on the processing

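Added after the data had been seen were a 3-parameter normexp fit, another liver baseline of the score and combination liver 742 left out. So were gene lists and divided covariances without each animal. The rank score was set beforehand and the others were planned. Of the planned refits of single genes, uncalled ones included, 9262 kept their direction and side of the limit. Another 266 lost a call, 12 gained one and 75 turned sign. Of those of counts, lists and scores 338 held, 87 weakened, 31 strengthened, 5 moved and 1 turned sign, judged for counts by size. The cause was not tested unless stated. Signal over background limits dim genes most: 28.9% of intensities lay below 0, the noise SD was 7.03, and the offset of 16 understates their differences. Chip as a block, planned, was not run, as the sources used here do not give it.

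Without background correction 16 genes passed in combination livers. With median scaling 0 passed between BEZ235 and RAD001 tumours, and 5 lists in RAD001 livers. With the deposited values Map1lc3b in combination livers turned to 0.0013, 0 genes passed between BEZ235 and RAD001 tumours and 1 for the tissue difference of RAD001. Without the filter 1 gene passed between combination and RAD001 tumours, 0 between BEZ235 and RAD001 tumours, and 0 for the tissue difference of RAD001. With the stricter filter 2 passed in RAD001 livers, 25 between BEZ235 and RAD001 livers and 4 for the tissue difference of BEZ235. With the mean over probes Rps19 turned to -0.24 in tumour against liver and -0.037 in combination livers, 0 genes passed between BEZ235 and RAD001 tumours and 2 for the tissue difference of the combination.

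With 1 tumour per animal, so fewer arrays, Igf2 (-0.44) and Sqstm1 (-0.043) turned in tumour against liver, Alb in BEZ235 (0.071) and combination tumours (-0.066), and Rhbg (0.10), Glul (0.39) and Fasn (-0.10) in RAD001 tumours. Then 1 gene passed between combination and RAD001 tumours, and 0 for the tissue differences of RAD001 and of the combination. With every tumour as its own array 1 gene passed in BEZ235 tumours, where Igf2 (-0.23) and Fasn (0.0070) turned, 10 in combination tumours, 7 between combination and RAD001 tumours, and 0 for the tissue difference of RAD001. With array weights Igf2 in BEZ235 tumours (-0.043) and Gpc3 (-0.047) and Cyp7a1 (0.15) in BEZ235 livers turned. Then 2 genes passed in RAD001 tumours, 1 in RAD001 livers, 6 between combination and RAD001 tumours, 42 between BEZ235 and RAD001 livers, and 2 and 4 for the tissue differences of BEZ235 and the combination. In a fit of only the groups compared 19 passed in combination livers, 46 between combination and RAD001 livers, 1 between combination and RAD001 tumours and 0 between BEZ235 and RAD001 tumours.

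With the animal as a fixed replicate block 2247 genes passed between placebo tumour and liver, in the 4 animals with both. With no block 1 passed for the tissue difference of RAD001, and no other count moved by over 1.5 times with the treatment of the block.

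The combination score difference crossed the limit at -0.257 with the 100 largest rises and falls, -0.247 without background correction, with the deposited values and with the other baseline, and -0.242 on ranks. In livers it was 0.0437 without 742, no longer past the limit. With an estimated correlation 0 lists passed in each of the 16 comparisons. Fry, for a common direction or for any change, gave 28 and 24 lists for tumour against liver, 0 in treated tumours, BEZ235 livers and RAD001 livers, 2 and 0 in combination livers, and 0 to 2 and 0 to 1 in the other 9 comparisons. With the placebo animals divided, the covariances of effects were 0.0291, 0.0375 and 0.0383 in tumours and -0.000929, 0.00936 and 0.00171 in livers, for BEZ235 with RAD001, BEZ235 with the combination and RAD001 with the combination.

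Leaving out 1 animal in turn, so fewer samples, gave 3257 to 3538 genes for tumour against liver, with Igf2 from -0.40 (710) to 1.15 (748), Sqstm1 from -0.12 (747) to 0.085 (696) and Fasn from -0.20 (710) to 0.077 (776). In BEZ235 tumours 0 to 2 genes passed (2 without placebo 748), with Igf2 from -0.21 (728) to 0.80 (755), Alb from -0.24 (710) to 0.081 (696), Fasn from -0.19 (755) to 0.043 (710) and Igfbp1 from -0.63 (728) to 0.017 (693). In RAD001 tumours 0 to 2 passed (2 without 727), with Igf2 from -0.14 (732) to 0.90 (727) and Fasn from -0.041 (747) to 0.20 (727). In combination tumours Map1lc3b ran from -0.077 (769) to 0.21 (726) and Alb from -0.21 (726) to 0.44 (773). In BEZ235 livers 0 (693 or 759) to 3 genes passed, with Afp from -0.32 (697) to 0.10 (748), Gpc3 from -0.17 (771) to 0.29 (712) and Cyp7a1 from -0.40 (693) to 0.22 (725). In RAD001 livers 0 to 1 passed (1 without 730), with Afp from -0.081 (745) to 0.40 (748), Sqstm1 from -0.0040 (710) to 0.073 (744), Cyp7a1 from -0.20 (771) to 0.22 (732) and Fasn from -0.021 (700) to 0.22 (776). In combination livers 14 (726) to 38 (713) passed, with Map1lc3b from -0.10 (775) to 0.0068 (709) and Glul from -0.20 (742) to 0.28 (773).

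Between treatments the counts without 1 animal were 1 to 2 for combination against RAD001 tumours (1 without RAD001 700, 727, 730 or 772 or combination 713, 726 or 775) and 0 to 1 for BEZ235 against RAD001 tumours (0 without BEZ235 693, 697, 712, 728 or 759 or RAD001 700, 727, 730, 732 or 772). In livers they were 47 (RAD001 760) to 92 for the combination against RAD001, and 6 (BEZ235 693) to 24 (BEZ235 755) for BEZ235 against RAD001. For the tissue difference of BEZ235 they were 0 to 4 (1 without 725, 3 without placebo 748, 4 without 712). For that of RAD001 they were 0 (730, 732 or placebo 710) to 3 (727), with 1 without 700, 745 or placebo 696, 747, 771 or 776. For that of the combination they were 0 (773) to 5 (775), with 2 without 742 or placebo 748 or 769 and 3 without 713 or placebo 710. Score differences ran from -0.251 (728) to -0.0989 (693) for BEZ235, -0.294 (727) to -0.172 (732) for RAD001 and -0.297 (775) to -0.130 (773) for the combination. Lists passing without 1 animal numbered 16 (placebo 710 or 747) to 20 for tumour against liver. In tumours they were 6 (placebo 747) to 13 (755) for BEZ235, 3 (730 or placebo 747) to 8 (placebo 696) for RAD001 and 10 (773, 775 or placebo 747) to 16 (placebo 748) for the combination. In livers they were 1 to 6 (755 or placebo 710), 6 (placebo 696 or 776) to 10 and 8 to 17 (709), in the same order. Between treatments they were in tumours 4 (726 or BEZ235 755) to 13 (773) for the combination against BEZ235, with 11 without 693, 5 to 10 against RAD001, and 1 (693) to 8 (712) for BEZ235 against RAD001, with 3 without 759, 727 or 772. In livers they were 0 (697) to 9 (759), with 3 without 725, then 3 (742) to 9, and 3 to 5. For the tissue differences of BEZ235, RAD001 and the combination they were 6 to 11, 0 (732) to 9 (placebo 748), with 7 without placebo 696 and 8 without 763, and 8 to 11. Covariances in tumours with the placebo animals divided ran from 0.0191 (693) to 0.0391 (727), 0.0215 (773) to 0.0449 (728) and 0.0166 (773) to 0.0494 (775).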

Other observations

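Liver scores, and lists without single animals, were computed only after the results they bear on had been seen. Lists were tested with camera (limma).

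Between placebo tumour and placebo liver, interferon response genes rose in 6 of 15 members, 7 adjusted over the list alone (camera adjusted p = 0.0816), fatty acid synthesis rose in 6 of 15 and fell in 3 by both counts (adjusted p = 0.669), and glycolysis rose in 4 of 13, 5 adjusted over the list alone (adjusted p = 0.197). Targets of p53 rose in 4 of 11 and fell in 1 by both counts (adjusted p = 0.169), and ribosome biogenesis rose in 4 of 14, 3 adjusted over the list alone (adjusted p = 0.454). Acute phase genes fell in 5 of 16 and rose in 3, 4 adjusted over the list alone (adjusted p = 0.95). NRF2 targets rose in 1 and fell in 2 of 15 (adjusted p = 0.559), hypoxia genes rose in 1 and fell in 2 of 11 (adjusted p = 0.907), and circadian genes rose in 1 and fell in 2 of 13 (adjusted p = 0.77). Of markers of other cells, endothelial genes rose in 3 of 14 and fell in 1 (adjusted p = 0.796), and 0 members passed among 8 T and NK cell (adjusted p = 0.559), 5 B and plasma cell (adjusted p = 0.88) and 6 neutrophil markers (adjusted p = 0.899). Female-biased genes rose in 2 of 8 and fell in 1 (adjusted p = 0.559), 1 of 4 acinar genes rose (adjusted p = 0.902), and 1 of 3 erythroid (adjusted p = 0.0906) and 1 of 3 adipocyte genes (adjusted p = 0.249) fell.

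Of the 40 lists, 7 passed for the combination against BEZ235 in tumours, 7 against RAD001 and 5 for BEZ235 against RAD001, with 5, 6 and 4 in livers and 9, 4 and 10 for the tissue differences of BEZ235, RAD001 and the combination, all lost with an estimated correlation. In mitosis genes combination tumours lay below BEZ235 (adjusted p = 4.7e-07) and RAD001 (adjusted p = 0.000242), 0 of 12 positive in both. Stellate and matrix genes also lay below both, and T, NK and endothelial markers below BEZ235. Against RAD001 they also lay below in interferon response genes (0 of 15 positive, adjusted p = 5.42e-05). They lay above in P450 genes (14 of 15 positive, adjusted p = 0.00124). BEZ235 tumours lay below RAD001 in oxidative phosphorylation (1 of 17 positive, adjusted p = 0.0118). In this order it was adjusted p = 0.509, 0.576, 0.576, 0.576 and 0.864 with an estimated correlation. Tumours 773 and 693 lay toward liver. The P450 call ended without 773 (adjusted p = 0.141) and both mitosis calls without 726 (0.116 and 0.355). That of oxidative phosphorylation ended without 732 (0.601) or 728 (0.108). Combination livers lay above BEZ235 in fatty acid synthesis (15 of 15 positive, adjusted p = 0.0369). They lay below it in interferon response genes (1 of 15 positive, adjusted p = 0.00268), beside higher neutrophil markers. BEZ235 livers lay above RAD001 in mitosis genes (11 of 12 positive, 3 adjusted over the list alone, adjusted p = 0.000288). P450 genes lay above RAD001 in BEZ235 (adjusted p = 0.000811) and combination livers (adjusted p = 9.54e-05), each with 2 members past the limit over all genes and 4 adjusted over the list alone. For these it was adjusted p = 0.622, 0.622, 0.363, 0.363 and 0.183 with an estimated correlation. The first call ended in 4 and the second in 2 of 13 fits without 1 animal (adjusted p up to 0.209 and 0.0876). The combination effect was more positive in tumour than in liver for oxidative phosphorylation, with 17 of 17 positive (adjusted p = 6.83e-05, adjusted p = 0.342 with an estimated correlation), and passed in all 16 fits without 1 animal, 773 included.

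Combination livers scored 0.0789 ± 0.0958 (SD, n = 7) against 0 ± 0.0360 in placebo (n = 7), 0 of 7 below its mean (exact permutation p = 0.0157, adjusted 0.0472). Without 742 they scored 0.0437 ± 0.0241 (n = 6, 0 of 6 below), no longer past the limit (exact permutation p = 0.0291, adjusted 0.0874). BEZ235 livers scored 0.0422 (exact permutation p = 0.146, adjusted 0.219) and RAD001 0.000753 (exact permutation p = 0.973). Placebo livers, unlike treated ones, helped choose the signature genes, so these tests decide nothing.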
